A study of Escherichia coli K-12 with 16 samples.

How the data were processed

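RNA was sequenced from 2 Escherichia coli K-12 strains, the tyrosine producer SDT387 and the reference SDT400, each grown in 2 reactors and sampled at 4 timepoints, which makes 16 libraries in 8 groups of 2. Per the labels' protocols, cultures were grown in 0.25 L Ambr fermenters at 37 °C and pH 6.5 with dissolved oxygen held at 40%, first as a batch of 150 mL with 5 g/L glucose monohydrate and then with a feed of 550 g/L at a set growth rate of 0.11 per h. Samples of 2 mL in the batch phase and 0.5 mL in the fed-batch phase went into 6 mL of RNAprotect, ribosomal RNA was removed, and stranded libraries were sequenced from both ends, again per the labels' protocols. Trim Galore, FastQC, Bowtie, featureCounts and MultiQC are named as tools per the submitters' processing notes, without versions or settings, and no genome build is named in the sources used here.

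The deposited values were log2 of TPM plus a pseudocount of 1, for 4355 genes and 16 columns, which was checked by taking them back to TPM: each column then summed to 1e+06. All 16 columns were used. Gene identifiers were locus tags, of which 4351 matched the reference annotation of assembly ASM584v2 (4238 protein-coding genes and 113 pseudogenes), which was used only for names, neighbouring genes and coding lengths; 4 genes had no name. TPM multiplied by coding length came in steps of a whole read, so that 99.18% to 99.34% of values were whole within 0.05 reads, and the reads on genes recovered in this way were 6081393 to 11270834 per library. A count of 0 was taken to allow up to 3 reads, which covers counting error only. TPM are shares of a library, so a change is relative to all other transcripts, and fold changes on the log2(TPM + 1) scale understate those of genes with low values.

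Genes with a mean of at least 5 TPM over the 16 libraries were tested, 3369 in all, on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes with a variance trend). Strain effects at each timepoint, changes from batch to early fed-batch and from early to late fed-batch within each strain, and the interaction of strain and timepoint came from 1 model of the 8 group means, with 8 residual and 2.56 prior degrees of freedom. The strain effect averaged over timepoints was tested on the means of the 4 reactors, with 2 residual and 3.47 prior degrees of freedom, since libraries of a reactor are repeated samples. Adjusted p-values are those of Benjamini and Hochberg within a comparison, with calls below 0.05. They measure the spread between these reactors, and with 2 reactors per strain each group holds 1 difference. From the design text and column names, libraries of the same number within a strain were taken as the same reactor. Sample titles name only replicates, and the averaged strain effect rests on this reading. Deviations of these libraries from the group means correlated at 0.0196 to 0.488 in SDT387 and at -0.184 to 0.162 in SDT400. The fits with a reactor block are therefore given beside a result where they move it. Between the strains the numbers pair nothing by the labels, and the same correlation ran from -0.774 to 0.316 there. All values within SDT400 lie inside that range, so they do not show that equal numbers are the same reactor. The averaged strain effect was not refitted with crossed numbers.

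Gene lists were 33, with 747 genes of which 743 matched, fixed with the tests, filters and alternatives before the data were examined. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; the count of a list's genes adjusted over the list alone is given beside that over all genes. Genes named in the text were chosen by a rule: the altered genes in every library, all members of the shikimate pathway and its tyrosine and phenylalanine branch for strain effects, the 5 largest differences per direction among calls with a mean of at least 20 TPM whose groups did not overlap, up to 4 members with the smallest adjusted p of each list described, and the 10 genes with the smallest adjusted p of the interaction test with a mean of at least 20 TPM. The strain effects given for tyrP and folA fall outside this rule and outside the counts of named calls.

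The code was tested on simulated data with the real means and 200 changed genes. In the comparisons of the 16 libraries 23% to 41% of genes changed 2-fold and 85% to 93% of those changed 4-fold were recovered, with 3 to 16 false calls. In the averaged strain effect these were 85% and 100% with 24 false calls, in the interaction 3% and 56% with 5, and camera called 0 of 100 unchanged lists for the strain effect at T2. The simulated noise was independent between genes and between libraries, also those of the same reactor, with the same spread in all libraries. These rates therefore do not carry over to lists of correlated genes or to groups of unequal spread. For the averaged strain effect they hold only if libraries of a reactor vary independently, and recovery is overstated where they vary together. Alternatives covered the pseudocount (0.1 and 10), the filter (none, or a mean of at least 50 TPM), median centring, quantile scaling, a 2-fold minimum, no variance trend, only the 4 libraries of a timepoint, reactor and replicate number as blocks, fed-batch timepoints alone, and leaving out each library or reactor in turn. A group left with 1 library was then assumed to vary like the others. Preparation and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Organic acid, tyrosine and biomass measurements were not analysed here.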

Results

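Transcript levels of 2 Escherichia coli K-12 strains were followed by RNA sequencing through a glucose fermentation. SDT387 was a tyrosine producer whose genotype label lists feedback-resistant aroG and tyrA, an altered aroB (aroBCO) and deletion of ptsHIcrr, the operon of the general components of the sugar phosphotransferase system (PTS). SDT400 carried the ptsHIcrr deletion alone and served as the reference strain. Each strain was grown in 2 reactors, and each reactor was sampled at 4 timepoints, in the batch phase (T1) and in the early (T2), middle (T3) and late (T4) fed-batch phase, which gave 8 groups of 2 libraries and 16 libraries in all. The number of reads on genes, recovered from the values, lay between 6081393 and 11270834 per library.

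Pairs of libraries from the same strain and timepoint differed in how close they were. Their correlation across genes was 0.995, 0.994, 0.955 and 0.988 at T1 to T4 in SDT387 and 0.901, 0.990, 0.935 and 0.994 in SDT400. In SDT400 at T1, 923 genes lay over 2-fold apart between reactors 1 and 2, against 497 at T3 in SDT400, 302 at T3 in SDT387 and 10 to 55 in the other groups. The library of SDT400 reactor 2 at T1 had 272 genes at 0, against 70 to 120 in the others, and ribosomal protein genes took 29.5% of its TPM, against 19.9% in reactor 1. At T3 the genes of sulfur assimilation were higher in reactor 1 than in reactor 2 of SDT387 (median log2 difference 2.97 over 21 genes) and lower in reactor 1 than in reactor 2 of SDT400 (-4.38).

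**Figure D1:**
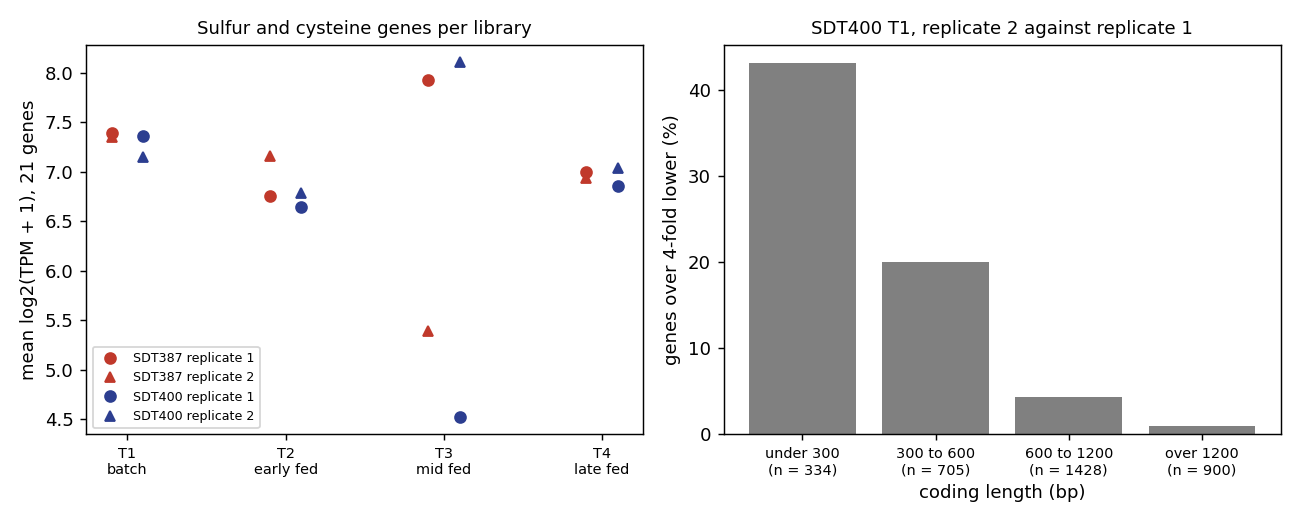
Left, mean log2(TPM + 1) of the 21 sulfur assimilation genes in each of the 16 libraries by timepoint. Right, percent of genes over 4-fold lower in SDT400 reactor 2 than in reactor 1 at T1, by coding length, which was 43.1% of genes under 300 bp and 1.0% of genes over 1200 bp.

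The genes altered by design were examined first in every library. No read of ptsI (b2416) or crr (b2417) was recovered in any of the 16 libraries, and ptsH (b2415) had 1 read, in SDT400 reactor 1 at T3 (0.345 TPM). In these libraries 3 reads of a gene of 900 bp would be 0.249 to 0.437 TPM. That floor is too low for ptsH, a shorter gene, whose 1 read was already 0.345 TPM. Transcripts of tyrA (b2600), which encodes chorismate mutase and prephenate dehydrogenase, averaged 13009 ± 2472 TPM in SDT387 and 45.8 ± 3.47 TPM in SDT400 (per reactor the mean over timepoints of log2(TPM + 1) taken back to TPM, then mean ± SD over reactors, n = 2), a log2 difference of 8.11 ± 0.19 SE (limma adjusted p = 0.00013). Those of aroB (b3389), which encodes 3-dehydroquinate synthase, averaged 21736 ± 2192 and 380 ± 2.84 TPM (5.83 ± 0.18, limma adjusted p = 0.00028), and those of aroG (b0754), which encodes a synthase of the first step of the shikimate pathway, 6189 ± 376 and 752 ± 13.9 TPM (3.04 ± 0.16, limma adjusted p = 0.0031). The 3 genes together held 3.12% to 4.93% of all TPM in the SDT387 libraries and 0.0946% to 0.147% in those of SDT400. At T1, T2, T3 and T4 the log2 difference was 6.98, 9.20, 7.94 and 8.30 for tyrA, 6.19, 5.96, 5.68 and 5.49 for aroB, and 2.61, 3.80, 2.74 and 3.00 for aroG, and every SDT387 library lay above every SDT400 library.

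**Figure D2:**
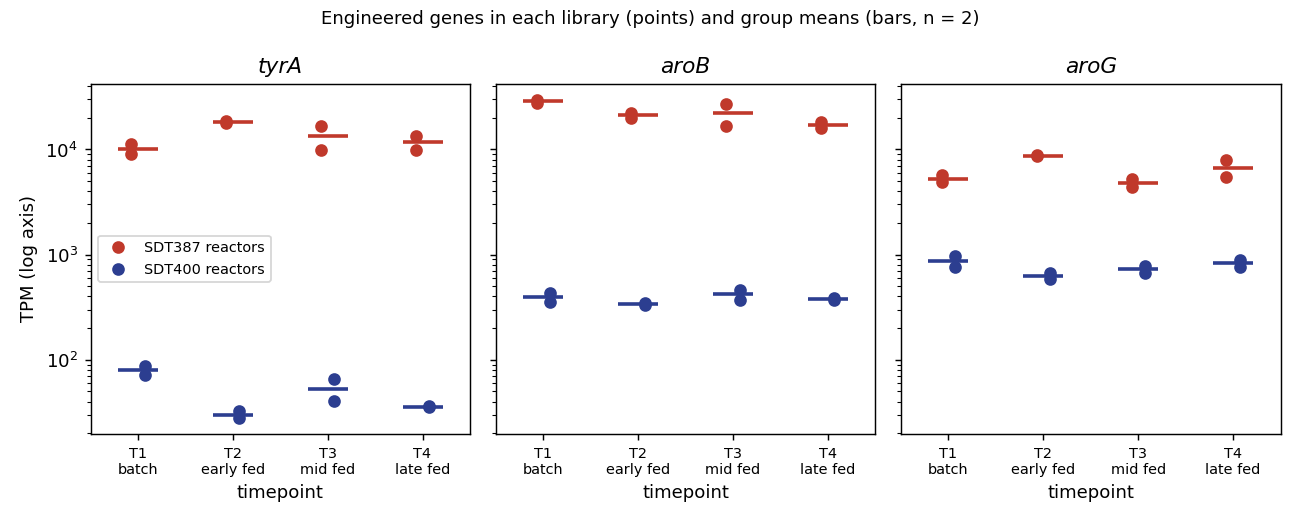
TPM of tyrA, aroB and aroG in each of the 16 libraries by timepoint, on a log axis, with bars at the group means. All SDT387 libraries sit above all SDT400 libraries for each of the 3 genes.

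The difference between producer and reference was next averaged over the 4 timepoints, to ask what else set the strains apart through the whole process. Beside the engineered genes, the largest differences above SDT400 were those of bhsA, which encodes a stress-induced outer membrane protein (2.91 ± 0.47 SE on the log2 scale, 1055 ± 201 against 155.6 ± 101.98 TPM, taken back from the log means of the reactors, n = 2 reactors per strain, limma adjusted p = 0.0499), and of ygiW, a gene for a periplasmic stress protein (2.58 ± 0.26, 546 ± 72.9 against 93.1 ± 31.9 TPM, limma adjusted p = 0.016). The value of bhsA, a gene of 258 bp, rests in part on SDT400 reactor 2 at T1. Its difference at T1 was 4.71 with that library and 2.32 without it. Lower in SDT387 were aroP, the general aromatic amino acid permease (-3.18 ± 0.15, 15.2 ± 1.75 against 145.8 ± 0.269 TPM, limma adjusted p = 0.0019), damX, a cell division gene of the operon that also holds aroB (-2.95 ± 0.19, limma adjusted p = 0.0044), flu, the surface antigen 43 (-2.38 ± 0.14, limma adjusted p = 0.0040), tyrB, the aromatic aminotransferase (-1.92 ± 0.26, limma adjusted p = 0.032), and fimA, the major subunit of type 1 fimbriae (-1.81 ± 0.15, limma adjusted p = 0.014). In all, 77 of 3369 genes passed, 41 higher and 36 lower in SDT387. The number of calls moved with the reactors used. Without reactor 1 or without reactor 2 of SDT387 there were 2 calls each, tyrA and aroB, without reactor 1 of SDT400 there were 644 (504 higher and 140 lower) and without its reactor 2 there were 130 (61 and 69), and of 26 named calls only those of tyrA and aroB held in all 4 of these fits. With the 16 libraries and the reactor as a random block the test gave 322 calls. Strain differs only between reactors, so pairing within reactors cannot sharpen this comparison. The fitted correlation within reactors was 0.0604, which treats repeated libraries of a reactor as nearly independent. With the 16 libraries taken as independent there were 428 calls.

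Of the 10 genes of the shikimate pathway, 2 were higher (aroG and aroB) and 1 was lower in SDT387, aroF, the tyrosine-sensitive isoenzyme of the aroG product (-1.38 ± 0.17 SE, limma adjusted p = 0.028; camera adjusted p = 0.42 for the list, whose median was -0.14 and mean 0.59). The other 7 genes lay between -0.53 for aroL (limma adjusted p = 0.23) and -0.01 for aroA and aroH, with aroD at -0.40, aroK at -0.36, aroC at -0.17 and aroE at -0.11, and did not pass. Of the 5 genes of the tyrosine and phenylalanine branch, tyrA was higher and tyrB lower, while pheA (-0.64, limma adjusted p = 0.18), aspC (0.05) and ilvE (0.21) did not pass (camera adjusted p = 0.94, with a lower direction against a median of 0.05, or -0.03 with median centring, and a mean of 1.16). Adjusted over the list alone, 1 gene of the branch was higher and 2 were lower. Among the 11 genes controlled by TyrR, the regulator of aromatic amino acid synthesis and transport, 4 were higher and 4 were lower. The higher ones were the engineered tyrA and aroG, the tryptophan permease gene mtr (1.92 ± 0.14, limma adjusted p = 0.0067) and folA (0.96). The lower ones included the tyrosine permease gene tyrP (-1.42). Adjusted over the list alone 4 were higher and 6 lower, and the list as a whole, with a median of -0.53 and a mean of 0.44, did not pass (camera adjusted p = 0.26). The engineered genes, changed by design, raise that mean.

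Of the 39 genes of iron uptake 9 passed as higher in SDT387, and 28 were higher when adjusted over the list alone, at a median log2 difference of 0.66. By timepoint the median was 1.12, 0.57, 0.05 and 0.85 at T1 to T4, and at T3 it was -0.04 with median centring. The iron list had camera adjusted p = 1.8e-15 and adjusted p = 0.61 with an estimated correlation. Examples were fes (1.40) and the enterobactin synthesis genes entB (1.34) and entH (1.54), and fecA, the outer membrane receptor of ferric citrate (1.34). In alternative carbon use, 1 of 35 genes was higher, tnaA for tryptophanase (1.23), and 3 were lower, the fatty acid degradation genes fadA (-1.31), fadE (-1.22) and fadB (-1.09), or 1 and 6 when adjusted over the list alone. The median of the carbon list was -0.37, 0.06, 0.01 and -0.55 at T1 to T4, and -0.29 in the averaged effect. The carbon list had camera adjusted p = 2.3e-06 and adjusted p = 0.72 with an estimated correlation. The acetate uptake genes actP (-1.30) and yjcH (-1.24) were the 2 lower genes of the 15 of pyruvate and acetate metabolism, where 3 were lower when adjusted over the list alone, and mtlA, the mannitol permease gene (-1.17), was the 1 lower gene of 29 in sugar PTS transport, with 7 lower when adjusted over the list alone. The acetate list had camera adjusted p = 0.0060 and adjusted p = 0.61 with an estimated correlation. The PTS list had camera adjusted p = 7.9e-06 and adjusted p = 0.61 with an estimated correlation. In aerobic respiration 0 of 28 genes passed with limma, 9 were lower and 1 higher at an unadjusted p under 0.05, and 8 were lower when adjusted over the list alone. The median of the respiration list was -0.46, -0.21, 0.07 and -0.14 at T1 to T4. The respiration list had camera adjusted p = 0.00027 and adjusted p = 0.61 with an estimated correlation. In all 14 of 33 lists passed with the preset correlation, 0 with an estimated correlation, where 0 had an unadjusted p under 0.05, and 3 with fry.

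At T1, in the batch phase, the comparison asked how the strains differed before the feed. The permease gene aroP was lower in SDT387 (-4.34 ± 0.30 SE on the log2 scale, 15.5 ± 2.1 against 341 ± 118 TPM, n = 2 per strain), as were aroF (-2.37 ± 0.25, limma adjusted p = 0.0005) and tyrP (-3.29), while mtr was higher (3.13 ± 0.31, 186 ± 4.44 against 20.6 ± 5.21 TPM, limma adjusted p = 0.00037). Of the 6 genes of tryptophan synthesis trpE, for the first enzyme, was higher (1.58 ± 0.16, limma adjusted p = 0.00037), and 4 were higher when adjusted over the list alone. The tryptophan list had camera adjusted p = 0.012 and adjusted p = 0.48 with an estimated correlation. Iron uptake had 4 of 39 genes higher, the ferric citrate genes fecA (2.54), fecB (1.79), fecC (1.80) and fecE (1.12), and 20 higher when adjusted over the list alone. The iron list had camera adjusted p = 1.3e-09 and adjusted p = 0.48 with an estimated correlation. In alternative carbon use 6 of 35 genes were lower, among them the maltose genes malK (-3.25), lamB (-2.91), malQ (-1.54) and malP (-1.52), and 9 were lower when adjusted over the list alone. The carbon list had camera adjusted p = 1.6e-05 and adjusted p = 0.54 with an estimated correlation. The malate:quinone oxidoreductase gene mqo was higher (2.43) and rpe, for ribulose-phosphate epimerase, was lower (-1.94).

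At T1 the stress gene bhsA was 4.71 ± 1.08 higher (limma adjusted p = 0.0499), or 2.32 without SDT400 reactor 2, the library with the most genes at 0, and appB (-2.57, limma adjusted p = 0.014) and appC (-2.56, limma adjusted p = 0.016) of cytochrome bd-II, and safA, of the EvgA signalling pathway (-2.35, limma adjusted p = 0.039), were lower. Without that library appB, appC and safA kept -2.28, -2.29 and -2.07 (limma adjusted p = 0.081, 0.094 and 0.17), and their adjusted p was highest without SDT387 reactor 1 at T1 (0.15, 0.15 and 0.28). In acid resistance 4 of 12 genes were lower, such as gadE (-2.18), slp (-1.92) and adiC (-1.63), 8 when adjusted over the list alone. Without SDT400 reactor 2 at T1 2 passed, with gadE at -2.18, slp at -2.19 and adiC at -1.31. The acid resistance list had camera adjusted p = 1.6e-05 and adjusted p = 0.30 with an estimated correlation. Of the genes of microaerobic growth 4 of 26 were lower, the hydrogenase genes hyaA (-1.20) and hyaB (-1.40) and appB and appC, 5 when adjusted over the list alone. Without that library 1 passed, hyaB at -1.25, with hyaA at -1.15. The microaerobic list had camera adjusted p = 0.0012 and adjusted p = 0.44 with an estimated correlation. Of the genes of nitrogen limitation 3 of 30 were lower, ddpB (-0.93), ddpC (-0.88) and astD (-1.46), 5 when adjusted over the list alone. Without that library none passed, with ddpB at -0.82, ddpC at -0.81 and astD at -1.33. Calls of gadE, slp, adiC, hyaA, ddpB, ddpC and astD were lost without 1 of the SDT387 libraries at T1. The nitrogen list had camera adjusted p = 3.2e-05 and adjusted p = 0.026 with an estimated correlation.

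The test at T1 called 84 of 3369 genes, 24 higher and 60 lower in SDT387 (limma, 8 residual degrees of freedom shared by all groups). The groups that share this spread were unequal. The log2 difference between reactors had an SD across genes of 1.14 in SDT400 at T1 and 0.24 in SDT387 at T1. With only the 4 libraries of T1 there were 2 calls, and with quality weights for the libraries 6. Without SDT400 reactor 2 at T1 there were 47 calls, 38 of them among the 84; without SDT400 reactor 1 at T1 there were 1480, of which the larger part was higher (1046 higher and 434 lower), without SDT387 reactor 1 or 2 at T1 there were 29 and 31, and without SDT400 reactor 1 or 2 at T3, which enter through the shared spread, there were 143 each. Of 40 named calls 16 held in all 16 fits without 1 library, those of tyrA, aroB, mtr, aroG, aroP, aroF, trpE, rpe, mqo, fecB, fecA, hyaB, malK, malQ, lamB and malP.

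In early fed-batch (T2), after the glucose feed had started, the branched-chain amino acid permease gene brnQ was 3.84 ± 0.25 SE higher on the log2 scale in SDT387 (595 ± 87.3 against 40.8 ± 7.09 TPM, n = 2 per strain, limma adjusted p = 1.3e-05), and ygiW was 3.10 higher (limma adjusted p = 0.014). Lower were damX (-3.57 ± 0.40, limma adjusted p = 0.0007), the purine permease gene xanP (-3.17, limma adjusted p = 0.014), yfdV (-3.11) and oxc (-3.07) of the oxalate operon, and yegR (-3.08). Of the aromatic pathway, aroL, for shikimate kinase (-1.65, limma adjusted p = 0.0072), tyrB (-2.19, limma adjusted p = 0.028) and aroP (-2.51) were lower. Of the 23 genes of purine and pyrimidine synthesis 6 were lower, with purT (-2.86), purM (-2.75), purK (-2.71) and purL (-2.37) as examples, and 9 when adjusted over the list alone. The purine list had camera adjusted p = 7.6e-09 and adjusted p = 0.65 with an estimated correlation. In aerobic respiration 5 of 28 genes were lower, the ATP synthase genes atpE (-1.11), atpB (-1.05), atpH (-1.01) and atpG (-0.97) among them, and 8 when adjusted over the list alone. The respiration list had camera adjusted p = 0.0035 and adjusted p = 0.65 with an estimated correlation. In tryptophan synthesis trpR, for the repressor (-1.98), and trpE (-0.72) were lower. The tryptophan list had camera adjusted p = 0.0083 and adjusted p = 0.65 with an estimated correlation. Higher were pgi, for glucose-6-phosphate isomerase (1.07), with 4 glycolysis genes higher when adjusted over the list alone, tnaA (2.26) and the glycerol-3-phosphate dehydrogenase gene glpD (1.03), and betA (0.77) and betB (0.71) of glycine betaine synthesis. The glycolysis list had camera adjusted p = 0.013 and adjusted p = 0.30 with an estimated correlation. The osmotic list had camera adjusted p = 0.021 and adjusted p = 0.30 with an estimated correlation.

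The test at T2 called 109 genes, 57 higher and 52 lower (limma). With only the 4 libraries of T2 there were 720 calls, and with quality weights for the libraries 922. The log2 difference between reactors at T2 had an SD across genes of 0.24 in SDT387 and 0.32 in SDT400. Since the spread is shared with wider groups, such as SDT400 at T1 (1.14), the counts do not rank the timepoints. Without 1 library of SDT387 at T2 there were 38 calls whichever was left out, without SDT400 reactor 1 or 2 at T2 there were 47 and 35, without SDT387 reactor 1 or 2 at T1 there were 68 each, without SDT400 reactor 1 or 2 at T1 there were 272 and 270, and without SDT400 reactor 1 or 2 at T3 there were 176 each. Of 32 named calls 11 held in all 16 fits without 1 library, those of tyrA, aroB, brnQ, aroG, damX, yegR, oxc, aroP, trpR, pgi and tnaA.

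In middle fed-batch (T3) the 2 amino acid permease genes mtr (3.37 ± 0.31 SE, limma adjusted p = 0.00024) and brnQ (3.14) were higher in SDT387, as was nfeR, the iron-responsive regulator of a ferric reductase gene (2.86 ± 0.25, 1158 ± 239 against 159 ± 34.6 TPM, n = 2 per strain). Lower were damX (-2.68), flu (-2.66 ± 0.17, 7.24 against 50.8 TPM), aroP (-2.61), the methylcitrate cycle gene prpD (-1.84), fimA (-1.59) and aroF (-1.47). In tryptophan synthesis trpE was 0.98 higher, and tnaA (1.43) and pgi (0.75) were higher as well. Of the 26 genes of envelope stress 1 was lower, pspE (-0.92; camera adjusted p = 1.3e-06, adjusted p = 0.16 with an estimated correlation). The test called 31 genes, 20 higher and 11 lower (limma). With only the 4 libraries of T3 there were 2 calls, and with quality weights for the libraries 15. At this timepoint the reactors of each strain lay apart in sulfur assimilation, with cysD at 1740 and 52.4 TPM in SDT387 reactors 1 and 2 and at 13.6 and 1856 TPM in SDT400 reactors 1 and 2. The 23 genes of purine and pyrimidine synthesis lay apart in the same reactors, by medians of 1.56 (SDT387 reactor 1 minus 2) and 1.36 (SDT400 reactor 2 minus 1), as did the ribosomal (0.54 and 0.62) and arginine (0.33 and 2.17) lists. The tryptophan (-1.61 and -0.57), acid resistance (-0.72 and -0.70), RpoS (-0.64 and -1.13), branched-chain (-0.72 and -0.64) and citric acid and glyoxylate cycle (-0.55 and -0.95) lists lay apart the other way. So did alternative carbon use (-0.37 and -0.81). Iron uptake lay apart by -0.76 and 1.135, and was thus higher in reactor 2 of both strains. Without SDT387 reactor 1 at T3 there were 15 calls, without SDT400 reactor 1 at T3 there were 51, without its reactor 2 at T3 there were 23 (10 higher and 13 lower), and without SDT400 reactor 1 or 2 at T1 there were 85 each. Of 16 named calls 8 held in all 16 fits without 1 library, those of tyrA, aroB, mtr, brnQ, nfeR, flu, aroP and aroG.

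In late fed-batch (T4) yhcN, a stress gene of the same family as bhsA, was 3.65 ± 0.62 SE higher in SDT387 (240 ± 82.5 against 17.6 TPM, n = 2 per strain, limma adjusted p = 0.010), and ygiW was 2.79 higher. Lower were damX (-3.52), aroP (-3.28), flu (-2.94 ± 0.17), and the phage shock genes pspD (-3.01 ± 0.36, 18.0 against 151 TPM, limma adjusted p = 0.0011) and pspB (-2.70). Of the aromatic branch pheA, for the bifunctional enzyme of phenylalanine synthesis (-1.29, limma adjusted p = 0.032), and tyrB (-2.20, limma adjusted p = 0.035) were lower. Of the 26 genes of envelope stress 5 were lower, with pspE (-1.84) a further example, and 1, bdm, was higher (2.01), or 6 and 2 when adjusted over the list alone. The envelope list had camera adjusted p = 0.00024 and adjusted p = 0.21 with an estimated correlation. In alternative carbon use 3 of 35 genes were lower, fadE (-2.49), fadA (-2.10) and fadB (-2.03), and tnaA was higher (1.37), or 6 and 1 when adjusted over the list alone. The carbon list had camera adjusted p = 5.6e-08 and adjusted p = 0.44 with an estimated correlation. Acetate genes actP (-1.84) and yjcH (-1.68), glcB (-1.31) and prpC (-1.78) were lower, and mqo (0.93) was higher. Of 15 osmotic stress genes proX, for the binding protein of the glycine betaine transporter, was higher (1.69), and 8 were higher when adjusted over the list alone. The osmotic list had camera adjusted p = 4e-05 and adjusted p = 0.040 with an estimated correlation. In glucose uptake outside the PTS galP was lower (-0.99), and 6 genes when adjusted over the list alone. The glucose uptake list had camera adjusted p = 0.00025 and adjusted p = 0.19 with an estimated correlation.

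The test at T4 called 95 genes, 46 higher and 49 lower (limma). With only the 4 libraries of T4 there were 581 calls, and with quality weights for the libraries 705. The log2 difference between reactors at T4 had an SD across genes of 0.35 in SDT387 and 0.24 in SDT400. Without reactor 1 or 2 there were 43 and 30 calls for SDT387 at T4, 35 and 23 for SDT400 at T4, 52 each for SDT387 at T1, 47 each for SDT387 at T2, 278 each for SDT400 at T1 (159 higher and 119 lower), 51 each for SDT400 at T2, and 163 and 164 for SDT400 at T3. Of 30 named calls 10 held in all 16 fits without 1 library, those of tyrA, aroB, aroG, damX, aroP, pspD, flu, mtr, fadE and pspE.

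Across the 4 timepoints 11 genes were called at each one in the same direction. Higher were tyrA, aroB, aroG, nemR, the electrophile-sensing repressor (1.48, 2.49, 2.01 and 2.41 at T1 to T4), and ygiV (1.86, 2.55, 2.42 and 2.48). Lower were aroP, flu (-2.25, -1.69, -2.66 and -2.94), fimA (-1.82, -2.004, -1.59 and -1.82), and the aroB operon genes damX, dam for DNA adenine methyltransferase (-1.51, -1.75, -1.49 and -1.69) and gph for phosphoglycolate phosphatase (-1.56, -1.16, -1.17 and -1.40); nemR, ygiV, dam and gph were singled out after their values were seen. In total 228 genes were called at 1 timepoint or more, 90 higher and 132 lower wherever they were called.

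Whether the strain difference itself moved with time was asked with an interaction test, which called 30 of 3369 genes. The tryptophan permease gene mtr stood 3.13, -1.15, 3.37 and 2.31 from SDT400 at T1 to T4, and trpE 1.58, -0.72, 0.98 and -0.00 (limma adjusted p = 0.0057 for both, n = 2 per strain and timepoint). The permease gene brnQ stood at 0.97, 3.84, 3.14 and 2.28 (limma adjusted p = 0.018), and the maltose gene malQ at -1.54, 0.19, 0.07 and -0.06 (limma adjusted p = 0.015). Differences that were near 0 or above it early in the process and below it later were those of prpD (0.14, 0.59, -1.84 and -2.18, limma adjusted p = 0.014) and the phage shock genes pspE (0.24, -0.08, -0.92 and -1.84, limma adjusted p = 0.014) and pspD (0.53, 0.05, -1.004 and -3.01, limma adjusted p = 0.027). The outer membrane porin gene ompF (-0.66, -2.99, -1.28 and -2.07), livG of branched-chain amino acid uptake (-0.33, -2.06, -0.73 and -0.51) and the porin pseudogene nmpC (-0.43, -0.82, -0.56 and -2.34) were the remaining genes of the 10 with the smallest adjusted p (limma adjusted p = 0.027 for each). The strain difference changed from T1 to T2 for 45 genes and from T2 to T4 for 8 genes (limma). These counts were not repeated under the alternatives or without a library, and the first uses SDT400 reactor 2 at T1. Between T1 and T2 the difference moved up in 7 of 35 genes of alternative carbon use, 9 when adjusted over the list alone, and in 3 of 30 genes of nitrogen limitation. The carbon list had camera adjusted p = 4.3e-05 and adjusted p = 0.67 with an estimated correlation. The nitrogen list had camera adjusted p = 1.5e-05 and adjusted p = 0.017 with an estimated correlation.

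Without reactor 1 or 2 the interaction test of limma called 1 and 3 genes for SDT387 at T1, 0 and 11 for SDT387 at T2, 13 and 11 for SDT387 at T4, 0 and 0 for SDT400 at T2, and 2 and 11 for SDT400 at T4, while without reactor 1 of SDT400 there were 930 at T1 and 114 at T3. With each reactor as a fixed block, so that the pairing of libraries within reactors was used, there were 2 calls. An unadjusted p under 0.05 was held by 373 genes with all libraries, and by 258, 297 and 276 in the 3 fits with 0 calls.

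**Figure D3:**
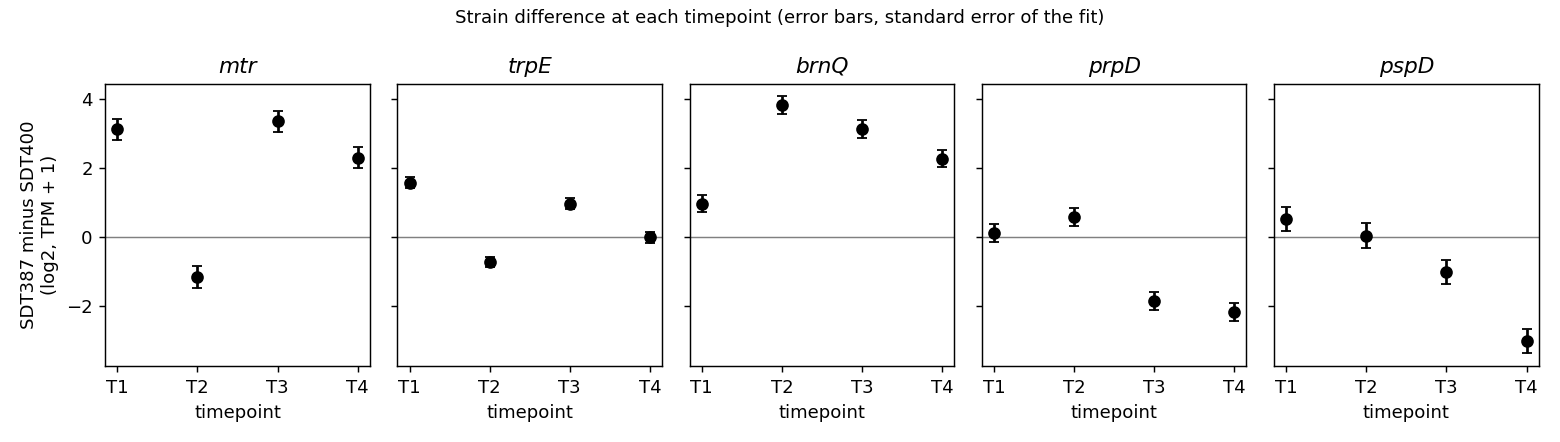
Log2 difference of SDT387 from SDT400 at T1 to T4 for mtr, trpE, brnQ, prpD and pspD, with bars of 1 SE from limma. The difference of mtr was 3.13 at T1 and -1.15 at T2, and that of pspD 0.05 at T2 and -3.01 at T4.

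The step from batch to early fed-batch (T1 to T2) was followed in each strain to see how the cells changed with the start of the feed. In SDT387 the methylcitrate cycle gene prpB rose by 6.33 ± 0.49 SE on the log2 scale (0.413 to 114 ± 25.4 TPM, n = 2 per timepoint, limma adjusted p = 1.1e-05), with prpC (5.61) and prpD (5.50), the biofilm regulator gene bssR rose by 6.06 ± 0.19 (46.0 to 3153 ± 372 TPM), and rmf, for the ribosome modulation factor of resting ribosomes, by 5.33 ± 1.65 (limma adjusted p = 0.023). The cobalamin-independent methionine synthase gene metE fell by 6.02 ± 0.41 (5439 ± 460 to 82.8 ± 2.61 TPM), as did borD (-4.90), yfdX (-4.77), ompF (-4.37) and purK (-4.30). In SDT400 prpB rose by 5.85 and metE fell by 6.29, and lower too were bioF of biotin synthesis (-3.51), carB for carbamoyl phosphate synthase (-3.48), borD (-3.67) and appC (-3.44). Higher too in SDT400 were rmf (9.83 ± 1.65), mcbA (6.92), ymdF (6.55) and pspC (5.67), which were 6.12, 4.28, 4.33 and 4.20 without SDT400 reactor 2 at T1, while prpB was 6.06. In that library rmf stood at 6.2 TPM against 1235 TPM in reactor 1.

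Ribosomal protein genes fell in both strains, 43 of 54 in each, 45 and 44 when adjusted over the list alone, at median log2 changes of -1.63 in SDT387 and -1.44 in SDT400. The ribosomal list had camera adjusted p = 1.7e-17 and 3.7e-16 and adjusted p = 0.27 and 0.40 with an estimated correlation. Genes of the general stress regulator RpoS rose, 22 of 28 in SDT387 and 21 in SDT400, 24 and 22 when adjusted over the list alone, with otsA of trehalose synthesis at 2.42 and 1.64. The RpoS list had camera adjusted p = 7.2e-06 and 0.0001 and adjusted p = 0.50 and 0.53 with an estimated correlation. Without SDT400 reactor 2 at T1 15 RpoS genes rose in SDT400. All 8 genes of histidine synthesis fell in both, also when adjusted over the list alone. The histidine list had camera adjusted p = 3.8e-05 and 5.2e-05 and adjusted p = 0.23 and 0.36 with an estimated correlation. Of the 28 genes of aerobic respiration 15 fell in SDT387 and 22 in SDT400, 15 and 23 when adjusted over the list alone, with cyoB of cytochrome bo at -2.29 and -2.16. The respiration list had camera adjusted p = 1.8e-07 and 1.8e-11 and adjusted p = 0.27 and 0.36 with an estimated correlation. In purine and pyrimidine synthesis 19 of 23 genes fell in SDT387 and 6 in SDT400, or 20 and 0 when adjusted over the list alone, and 1 fell in SDT400 without its reactor 2 at T1. The purine list had camera adjusted p = 2e-09 and 5.2e-05 and adjusted p = 0.41 and 0.53 with an estimated correlation. In arginine synthesis 7 and 11 of 12 genes fell, as many as when adjusted over the list alone. The arginine list had camera adjusted p = 0.0011 and 8.8e-06 and adjusted p = 0.52 and 0.47 with an estimated correlation. The genes of microaerobic growth went both ways, with 11 of 26 higher and 8 lower in SDT387 and 5 higher and 9 lower in SDT400, or 11 and 8, and 6 and 9, when adjusted over the list alone. Among them the nitrate respiration genes narK (-4.10 and -4.47) and narG (-2.90 and -3.41) fell. The microaerobic list had camera adjusted p = 0.69 and 0.024 and adjusted p = 0.91 and 0.51 with an estimated correlation.

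For these groups and those that follow, whether the strains differed was tested only by the interaction. In alternative carbon use 24 of 35 genes rose and 0 fell in SDT387, while 20 rose and 7 fell in SDT400, with fadB at 3.80 and 3.75, fadE at 3.59 and 3.77, and malK at -2.90 in SDT400. Adjusted over the list alone 26 rose in SDT387, and 20 rose and 8 fell in SDT400. The carbon list had camera adjusted p = 2.3e-05 in SDT387, with adjusted p = 0.50 with an estimated correlation, and 0.17 in SDT400. In iron uptake 16 of 39 genes rose and 4 fell in SDT387 and 22 rose in SDT400, with sufB of iron-sulfur cluster assembly at 2.56 and 2.20. In SDT400 24 rose when adjusted over the list alone, and in SDT387 16 rose and 4 fell. The iron list had camera adjusted p = 0.083 in SDT387 and 5.2e-05 in SDT400, in SDT400 with adjusted p = 0.53 with an estimated correlation. All 6 tryptophan synthesis genes fell in SDT387 and 2 in SDT400, or 1 in SDT400 without its reactor 2 at T1, with trpE at -3.42 and -1.12. The tryptophan list had camera adjusted p = 6.6e-05 in SDT387, with adjusted p = 0.27 with an estimated correlation, and 0.069 in SDT400. In branched-chain amino acid synthesis 6 of 17 genes fell in SDT387 and 2 in SDT400, ilvC at -4.16 and -2.84. The branched-chain list had camera adjusted p = 0.0013 in SDT387, with adjusted p = 0.50 with an estimated correlation, and 0.17 in SDT400. Of 17 flagellar genes 11 rose in SDT387 and 12 in SDT400, 12 and 14 when adjusted over the list alone, and without SDT400 reactor 2 at T1 7 rose and 1 fell in SDT400. The flagellar list had camera adjusted p = 0.0049 and 0.0026 and adjusted p = 0.50 and 0.47 with an estimated correlation. In nitrogen limitation 15 of 30 genes rose in SDT387, astA by 3.67, while 17 rose and 4 fell in SDT400, and in phosphate limitation 11 of 16 rose in SDT387 and 5 rose and 1 fell in SDT400, phoH by 3.03 and 2.48. Adjusted over the list alone 16 nitrogen genes rose in SDT387, and the other counts of the tryptophan, branched-chain, nitrogen and phosphate lists were equal to those over all genes. The nitrogen list had camera adjusted p = 0.0021 in SDT387, with adjusted p = 0.16 with an estimated correlation, and 0.22 in SDT400. The phosphate list had camera adjusted p = 0.0017 in SDT387, with adjusted p = 0.19 with an estimated correlation, and 0.28 in SDT400.

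The test called 1506 genes in SDT387, 971 higher and 535 lower at T2, and 1454 in SDT400, 930 and 524 (limma). Centring each library on its median, which shifted the median change of all genes by -0.206 and -0.229, gave 798 higher and 726 lower in SDT387 and 737 and 724 in SDT400, and quantile scaling gave 715 and 726, and 628 and 740. Between the strains, which share no library, 644 genes were higher in both against 268 expected of independent lists, 343 were lower in both against 83.2, and 12 went opposite ways. Both lists came from the same fit with a shared spread per gene. They were thus not independent, and the expected counts serve only as a scale. Without SDT387 reactor 1 at T2 there were 1002 calls in SDT387, and without SDT400 reactor 1 or 2 at T2 there were 648 and 895 in SDT400; without SDT400 reactor 2 at T1 there were 1082 (591 higher and 491 lower), 925 of them among the 1454, and without its reactor 1 there were 2032 (1439 and 593). Of the named calls 107 of 128 held in SDT387 and 95 of 123 in SDT400 in all fits without 1 library; of the genes named here rmf in SDT387 was lost in 4 and carB in SDT400 in 1, with limma adjusted p of up to 0.093 without SDT387 reactor 2 at T2 and 0.061 without SDT400 reactor 1 at T2.

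**Figure D4:**
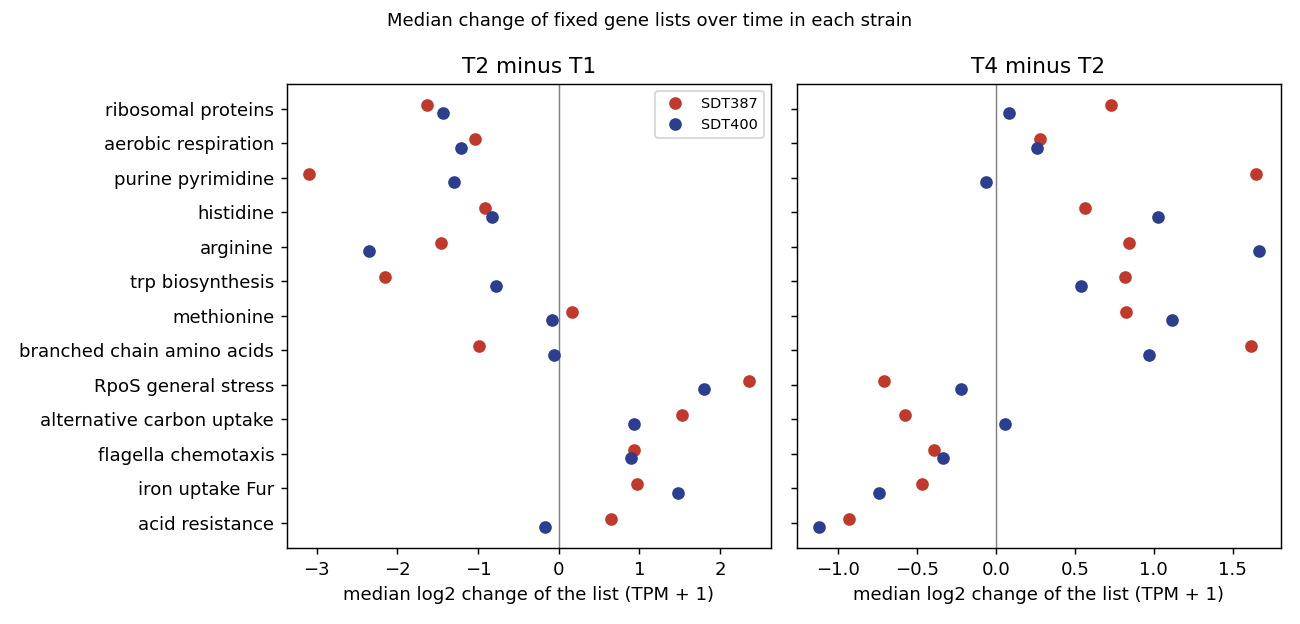
Median log2 change of 13 gene lists from T1 to T2 and from T2 to T4, for SDT387 and SDT400. Ribosomal protein genes lay at -1.63 in SDT387 and -1.44 in SDT400 for T1 to T2.

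From early to late fed-batch (T2 to T4) the question was how each strain changed as the feed went on. The methionine synthase gene metE rose again, by 4.65 ± 0.41 SE in SDT387 (82.8 ± 2.61 to 2123 ± 424 TPM, n = 2 per timepoint) and by 4.89 ± 0.41 in SDT400 (61.2 ± 13.9 to 1814 ± 67.8 TPM), with bioB of biotin synthesis at 4.31 and 3.19 (limma adjusted p = 0.049 in SDT400). In SDT387 mtr (3.80), bioF (3.69) and proV of the glycine betaine transporter (3.48) rose, and prpB (-5.80), prpD (-4.92), prpC (-4.70), pspD (-3.27) and pspG (-3.26) fell. In SDT400 the colanic acid synthesis genes wzb (3.04), gmd (2.94) and fcl (2.93) rose, and yncJ (-3.00), prpB (-2.70), the glutaminase gene glsA (-2.59), the acid resistance regulator gene gadE (-2.47) and prpC (-2.25) fell.

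Genes of methionine synthesis rose in both strains, 5 of 13 in SDT387 and 7 in SDT400, 7 and 11 when adjusted over the list alone, with metF at 1.95 and 2.25. The methionine list had camera adjusted p = 4.9e-06 and 1.7e-12 and adjusted p = 0.088 and 0.0078 with an estimated correlation. In histidine synthesis 3 and 8 of 8 genes rose, 7 and 8 when adjusted over the list alone. The histidine list had camera adjusted p = 0.00029 and 7.6e-12 and adjusted p = 0.23 and 0.027 with an estimated correlation. In branched-chain amino acid synthesis 7 and 2 of 17 rose, 13 and 3 when adjusted over the list alone, ilvC by 2.74 and 1.58. The branched-chain list had camera adjusted p = 1.2e-06 and 0.00034 and adjusted p = 0.37 and 0.57 with an estimated correlation. In purine and pyrimidine synthesis 8 of 23 genes rose in SDT387, 12 when adjusted over the list alone, and 0 in SDT400 with limma, where 0 were also counted at an unadjusted p under 0.05. The purine list had camera adjusted p = 1.2e-06 in SDT387, with adjusted p = 0.41 with an estimated correlation, and 0.79 in SDT400. In acid resistance 5 and 2 of 12 genes fell, 5 and 4 when adjusted over the list alone. The acid resistance list had camera adjusted p = 0.0011 and 2e-05 and adjusted p = 0.39 and 0.42 with an estimated correlation. The envelope list split, with 7 of 26 genes higher and 9 lower in SDT387 and 6 and 1 in SDT400, or 7 and 11, and 6 and 4, when adjusted over the list alone. In it colanic acid genes rose in both, and the phage shock genes pspD and pspG fell in SDT387. Phage shock genes were not tested as a group. The envelope list had camera adjusted p = 0.71 and 0.24. Iron uptake had 3 and 2 of 39 genes lower, 2 and 4 when adjusted over the list alone, with fecA at -2.01 and -1.65. The iron list had camera adjusted p = 0.0011 and 1.4e-07 and adjusted p = 0.60 and 0.57 with an estimated correlation. Of the osmotic genes proX (3.43) and proW (2.85) rose in SDT387.

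The test called 375 genes in SDT387, 190 higher and 185 lower at T4, and 143 in SDT400, 104 and 39 (limma). Without reactor 1 or 2 the calls in SDT387 were 89 (62 higher and 27 lower) and 119 for SDT387 at T2, 153 and 89 (59 and 30) for SDT387 at T4, 243 each for SDT387 at T1, 806 and 805 for SDT400 at T1, 573 each for SDT400 at T3 and 248 each for SDT400 at T4. The calls in SDT400 were 40 and 65 without reactor 1 or 2 of SDT400 at T2, 38 and 51 at T4 and 348 and 350 at T1, and 89 and 91 without either reactor of SDT387 at T1 and at T2. Of the 79 named calls in SDT387 23 held in all 16 fits without 1 library, and of the genes named here these were metE, mtr, bioF, proV, prpB, prpC, prpD, pspD, pspG, ilvC, proX and proW; of the 34 in SDT400 10 held, metE, wzb, gmd, fcl, metR, hisC, hisG, wzc, yjfN and bssR. Between the strains 70 genes were higher in both against 5.9 expected of independent lists, 25 were lower in both against 2.1, and 0 went opposite ways. These lists too came from the same fit with a shared spread per gene and were not independent.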

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

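Of the tests in this part, only those of the interaction and of the depth of SDT400 reactor 2 at T1 were chosen before the result they measure was seen, and all others were chosen after it. The strain difference itself changed with time, by limma's interaction test, for 30 genes, from T1 to T2 for 45 genes and from T2 to T4 for 8 genes. The 10 genes named for it went by adjusted p, and a difference between timepoints is what brought each of them here. For mtr (adjusted p = 0.005727) and trpE (adjusted p = 0.005727) the strain difference was above 0 at T1 and T3 and below 0 at T2. For malQ (adjusted p = 0.01482) it lay at -1.54 at T1 and within 0.2 of 0 later, and for brnQ (adjusted p = 0.01796) it was largest at T2. For pspE (adjusted p = 0.01387), prpD (adjusted p = 0.01387), pspD (adjusted p = 0.02673) and the pseudogene nmpC (adjusted p = 0.02673) it was lowest at T4. For livG (adjusted p = 0.02673) and ompF (adjusted p = 0.02673) it was lowest at T2. With a fixed reactor block, which uses the pairing within reactors, 2 genes were called by the interaction test.

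The library of SDT400 reactor 2 at T1 lay far from that of reactor 1, with 923 genes over 2-fold apart. A lower depth was argued against, since 28.29% of the 1488 genes with a mean of at least 100 TPM were over 2-fold apart against 27.4% of all genes, and the library had the 8th lowest number of reads. Its tyrA level of 87.6 TPM argued against a library of SDT387. The correlation across genes with the change of SDT387 from T1 to T2 was -0.1241. That change spans the start of the feed, so it cannot decide on an earlier or later sample within the batch phase. Against reactor 1, rmf was lower (6.2 against 1235 TPM) and the ribosomal protein share higher (29.5% against 19.9%), both opposite to the change from T1 to T2. Sampling at another point thus stays open. A loss of short genes stays open as a candidate explanation for part of it: the difference of reactor 2 from reactor 1 rose with coding length (Spearman rho = 0.3812 across 3367 genes, which are not independent replicates, against -0.0703 to 0.122 in the other pairs), and 43.1% of genes under 300 bp but 1.0% of those over 1200 bp were over 4-fold lower. The higher ribosomal protein share goes against a loss of all short genes, since this group holds short genes such as rpsL (375 bp) and rpsF (396 bp). Within the group rplS went the other way, at 20.67 against 1691 TPM in reactor 1. A real difference between the reactors also stays open and was not tested.

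At T3 the 21 genes of sulfur assimilation lay apart between the reactors of both strains, by 2.97 in SDT387 and -4.38 in SDT400 (reactor 1 minus reactor 2, log2). Exchanged strain labels were argued against by tyrA, at 9907 TPM or more in both SDT387 libraries against at most 65.6 TPM in SDT400. The list lay at least 2.948 from the median of all genes in both strains. That gap cannot decide on depth, since TPM scale each library to the same total and the list was picked for lying apart. The list mean of the lower reactor of each strain lay at least 1.553 below both its T2 and its T4 value. The higher reactors lay above both, at 7.925 against 6.753 and 6.997 in SDT387 reactor 1. In SDT400 reactor 2 these were 8.106 against 6.789 and 7.038. For these genes this argued against a sample taken earlier or later on a steady course, in either reactor. The list was picked for its gap at T3, which limits this argument, and the values do not tell which reactor was unusual. No biological explanation was tested, since the design names no difference between the reactors of a strain.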

How the results depend on the processing

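Voom on recovered reads, quality weights, fits on other timepoints, the 600 bp minimum, the crossed pairing, and the list fits with a block or without a library were chosen after the data were seen. Numbers are calls, and for the counts that moved the cause was not tested except where fewer genes or libraries entered. A pseudocount of 10 gave 51 for the interaction and 136 for the averaged effect. A mean of at least 50 TPM, with fewer genes, gave 28 at T1, 56 at T4, 875 and 888 for batch to early fed-batch in SDT387 and SDT400, 222 for early to late in SDT387, 13 for the interaction and 45 for the averaged effect. Only the 4 libraries of a timepoint gave 2, 720, 2 and 581 at T1 to T4. The averaged effect had 428 calls with 16 independent libraries, 211 in fed-batch timepoints, 197 with voom (72 of the 77 shared) and 869 at T2 and T4 (73 shared). Quality weights gave 6, 922, 15 and 705 at T1 to T4, 2558 and 271 for batch to early fed-batch, 1469 and 1067 for early to late, and 1 for the interaction. Libraries of T2 and T4 alone gave 732 at T2, 789 at T4, and 1511 and 860 for early to late. Without the T3 libraries there were 275 at T1, 263 at T2, 273 at T4, and 796 and 277 for early to late. Genes of at least 600 bp gave 131 at T1. Of the lists, 0, 0 and 1 passed with an estimated correlation for the averaged effect, batch to early and early to late fed-batch (0, 5 and 4 at an unadjusted p under 0.05), and with fry 3 and 26 in the first 2.

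Reactor as a random block gave 322 for the averaged effect, and as a fixed block 2 for the interaction; with the SDT400 numbers crossed at T3, where the pairing correlation of T3 with T4 was -0.184, the interaction had 12. Other counts moved by at most 1.5 times with these blocks, as did those at T1 to T4 and of the interaction with the replicate number as a replicate block (99, 110, 31, 85 and 30).

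Without 1 library or reactor each, counts ranged from 29 to 1480 at T1, 35 to 272 at T2, 15 to 85 at T3, 23 to 278 at T4, 1002 to 1986 and 648 to 2032 for batch to early fed-batch, 89 to 806 and 38 to 350 for early to late, 0 to 930 for the interaction, 2 to 644 for the averaged effect, and for lists 9 to 15, 11 to 17 and 16 to 18. Of 508 named calls 282 held in every such fit and 0 changed sign. Of the 508, 492 held with a pseudocount of 0.1, 500 with 10, 469 with centring, 457 with quantile scaling and 490 with voom, and 0 reversed. Counts stayed within 1.5 times of the reported ones with a pseudocount of 0.1, no filter, centring, quantile scaling, a 2-fold minimum and no variance trend. At this depth 3 reads of a gene of 900 bp were 0.249 to 0.437 TPM, which limits what a count of 0 excludes.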

Other observations

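All tests in this part, of gene groups and of explanations, were chosen after the results were seen. Genes activated by EvgA, an acid and drug response regulator (13 genes, among them yfdX, oxc, frc, emrK, emrY, safA and ydeP), were lower in SDT387 averaged over timepoints, 9 of 13 at a median of -1.32 with limma. By timepoint 3 were lower at T1 and 8 at T2, and none passed at T3 and T4, with medians of -1.24, -2.53, -1.38 and -0.20. From batch to early fed-batch 10 of 13 fell in both strains, with medians of -3.32 in SDT387 and -1.86 in SDT400. From early to late fed-batch 7 were higher and 1 lower in SDT387 (median 2.10), and 0 were higher and 2 lower in SDT400. The 3 aae genes of hydroxybenzoic acid efflux were all higher in SDT387 at T2, T3 and T4 and none passed at T1, with aaeX at 0.40, 3.28, 2.89 and 2.75 at T1 to T4, aaeA at 0.24, 1.43, 1.39 and 1.67 and aaeB at 0.15, 1.13, 1.01 and 1.00. Of the 3 genes controlled by NemR 2 were higher in the averaged effect, with a median of 1.35. The 19 genes of colanic acid synthesis fell from batch to early fed-batch, 19 in SDT387 (median -1.69) and 15 in SDT400 (-0.999), and all 19 rose from early to late fed-batch in both (2.54 and 2.59).

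Of the 5 genes that follow aroB in its operon, damX, dam, rpe and gph were lower in SDT387 in the averaged effect and trpS did not pass (-0.67 ± 0.14 SE), at a median of -1.475 for the 5. A dilution of TPM by the engineered transcripts was argued against, because these held at most 4.93% of TPM in an SDT387 library. The 5 genes lay at -1.557 from the median of all tested genes, but that gap is what they were picked for. A position effect of the altered aroB locus is a candidate explanation that stays open: aroK, which precedes aroB, lay at -0.36 ± 0.18 SE, 1.11 above the median of the 5 genes that follow it, though within 2 SE of trpS. The design holds no strain with the aroB change alone, so an effect of the whole producer background on these genes stays open too and was not tested.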
